A study of Arabidopsis thaliana with 18 samples.

How the data were processed

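Total RNA of rosette leaves had been extracted with Trizol and made into libraries with a stranded mRNA kit (Illumina TruSeq), per the labels' protocols. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the genome build TAIR10 and counted with HTSeq 0.6.1. The deposited values are raw read counts per gene, 1 file per library, without normalization. Each file held counts for 37336 plant genes and 7 viral genes, followed by 5 HTSeq summary lines with the reads that did not align, aligned in several places or met no gene. The values were checked to be whole numbers, and the genes to be in the same order in all files. The labels do not state the annotation, the read length, the strand setting of the counting, the hour of harvest, or whether the 3 libraries of a group come from separate plants. Overlapping and antisense genes are uncertain for this reason.

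Gene names were taken from a RefSeq table of assembly TAIR10.1, matched on the locus identifier. Since this assembly differs in version from TAIR10, no coordinates are given. Names were found for 37051 of the 37336 plant genes, and the 285 others are genes of the chloroplast or mitochondrion. Groups were taken from the sample titles: mock or TuYV inoculation at 0, 6 or 72 h of aphids, 3 libraries in each of 6 groups.

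Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust dispersion, TMM scaling) in 1 fit of 6 group means to all 18 libraries, which leaves 12 residual degrees of freedom. Genes were kept with edgeR's expression filter at a minimum count of 10 and a minimum total of 15, which left 19515 genes. The common biological coefficient of variation was 28.7%. Reads assigned to plant genes ranged from 11946011 to 20652435 per library. A prior count of 2 was used for log2 CPM. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 10 comparisons were TuYV minus mock at each of the 3 times and averaged over them, 6 h and 72 h minus 0 h within each inoculum, and the interaction at 6 h and at 72 h. P-values were adjusted over genes with the Benjamini-Hochberg method within each comparison, and genes below 0.05 were called. Single measures of the libraries were compared with 2-sided exact permutation tests. Where a viral count was 0, 3 counts were taken as the upper limit, which covers counting error only, since reads are not independent molecules.

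The comparisons, the test, the filter, 22 gene lists with 352 genes and the rule for naming genes were fixed before the data were examined, as were the alternatives except those named as later. The lists cover defence hormones (salicylic acid, jasmonate, ethylene, abscisic acid), defence compounds (camalexin, indole and aliphatic glucosinolates, flavonoids), early defence, RNA silencing, heat shock, endoplasmic reticulum stress and senescence. They further cover light reactions, the Calvin cycle, starch and sugar, morning and evening clock genes, and markers of phloem, guard cells, epidermis and flowering. All 352 listed genes were found in the files and 332 were tested. Lists with at least 5 tested members were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over lists within a comparison. Members were counted as called over all genes and when adjusted over the list alone. Genes were named from the 5 rising and 5 falling called genes with the largest change, from up to 4 called members of each list with the smallest adjusted p, and from 8 genes set in advance (PR1, LOX2, VSP2, PDF1.2a, PAD3, AGO2, RDR1 and CCA1). The largest changes were taken among genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the compared groups. For the interactions the overlap was not required, and for the averaged comparison the same sign was required at all 3 times instead.

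Alternatives were RLE scaling, no filter on low counts, a stricter filter (at least 1 CPM in every library of a group and a mean of at least 5 CPM), the replicate number as a block, organelle genes left out, only the compared groups in the fit, the Wald test of DESeq2 1.42.0, and each library left out in turn. Further alternatives were chosen after seeing the data: the mean levels of both clock lists as covariates in the virus comparisons, these covariates and the replicate block each with an estimated correlation for lists, and the replicate block together with only the compared groups for the virus comparison without aphids. Whether replicate numbers pair the libraries was checked from the correlation of same-numbered libraries after removal of group means, with a minimum of 0.1 in every pair. This held for the virus at 72 h (0.310 to 0.546) and for aphids at 72 h on TuYV plants (0.235 to 0.469), whose blocked counts are given. Over all libraries, the best match outside the group had the same number for 13 of 18. This was so for 6 of 6 libraries numbered 1, 1 of 6 numbered 2 and 6 of 6 numbered 3. In the other comparisons only pairs numbered 2 fell short of the minimum. For the virus without aphids the correlations were 0.717, 0.0835 and 0.601 for numbers 1, 2 and 3. Libraries numbered 1 and 3 thus deviated together there too, while the main fit has no block.

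The tests across genes were tried on counts simulated from the means and spread of these libraries. They held 100 genes with a log2 change of 1 and as many with 2. In the order virus at 0, 6 and 72 h, aphids at 6 and 72 h on mock plants, aphids at 6 and 72 h on TuYV plants, interactions at 6 and 72 h, and averaged virus, the tests recovered 22, 36, 28, 21, 33, 32, 31, 11, 4 and 79% of the genes with a log2 change of 1. They recovered 77, 81, 82, 81, 84, 79, 84, 63, 61 and 95% of those with a log2 change of 2. Between 2 and 8 unchanged genes were called per run of 19297 to 19348 genes. Of 200 random lists per comparison, 0 to 7 had a camera p below 0.05. Neither result covers libraries that deviate together, as here, or lists whose genes do. Unaligned reads were only counted, since the files hold no sequences.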

Results

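Gene expression was measured by mRNA sequencing in rosette leaves of Arabidopsis thaliana of the Col-0 ecotype, the reference accession of the species. Plants had received a mock inoculation or turnip yellows virus (TuYV), a phloem-limited virus that aphids carry from plant to plant. They were sampled at 0, 6 or 72 h of infestation with the green peach aphid Myzus persicae. The 6 groups held 3 libraries each, 18 in all, with 11946011 to 20652435 reads each assigned to plant genes. Log2 fold changes are given ± SE from the fit to all libraries, and levels in CPM, the read counts scaled to library size, as mean ± SD with n = 3 libraries per group. Levels of near-identical copies are uncertain, since their reads can be split between them. This concerns LHCB1 and LHCB2 genes, RBCS2B, the pair CYP79F1 and CYP79F2, the pair VSP1 and VSP2, and the BIP and small heat shock protein genes. Called gene lists were tested again in further settings: RLE scaling, each compared library left out in turn and, in the virus comparisons, the levels of both clock lists as covariates. The fit with covariates was chosen after seeing the data and is not counted for the clock lists themselves. Where the call of a list ended in any of them, their number is given with the highest adjusted p.

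Viral reads were examined first, as a check of the inoculum only, since capture of viral RNA by the mRNA kit was not tested. No count of the 7 viral genes was found in any of the 9 mock libraries, where 3 counts would have been at most 0.194 CPM of the plant counts. All 9 TuYV libraries held viral counts, at 4.75 ± 0.929 CPM of the plant counts at 0 h, 4.34 ± 1.60 at 6 h and 4.59 ± 1.36 at 72 h (SD, n = 3). The levels at 6 h and 72 h differed from that at 0 h by less than the spread between libraries (2-sided exact permutation p = 0.8 and 0.9, where 0.1 is the smallest value that 3 against 3 libraries allow).

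Reads that did not align to the plant genome were more frequent in the libraries with aphids. Their share was 0.880 ± 0.0860% in Mock-0h and 0.984 ± 0.377% in TuYV-0h libraries (SD, n = 3). It was 3.47 ± 0.350% in Mock-6h, 2.94 ± 0.590% in Mock-72h, 3.90 ± 1.44% in TuYV-6h and 4.85 ± 2.77% in TuYV-72h libraries (SD, n = 3). The 12 libraries with aphids exceeded the 6 without by 2.86 percentage points (2-sided exact permutation p = 5.39e-05, the smallest that 18564 splits allow).

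**Figure D1:**
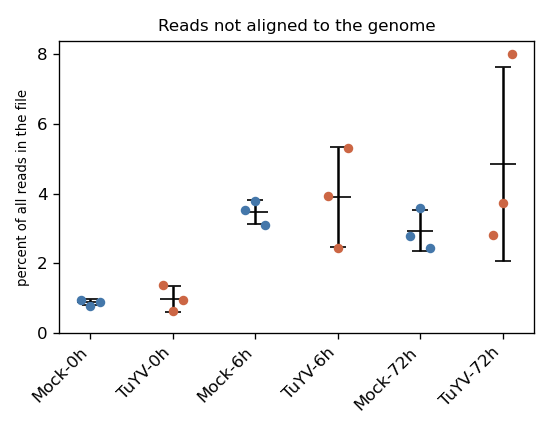
Share of reads in each library that did not align to the plant genome, in percent, with 1 point per library, the group mean as a horizontal mark and the SD as error bars (n = 3), mock in blue and TuYV in orange. The libraries without aphids average 0.880% and 0.984%, below each of the groups with aphids.

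TuYV plants without aphids were compared with mock plants at 0 h. Of the flavonoid list, 12 of 14 tested members fell, and 13 fell when adjusted over the list alone. The list was lower in TuYV plants (median -2.43, adjusted p = 6.10e-17, and 0.0292 with an estimated correlation). Mock-0h lay above all other groups, and its growth or harvest conditions stay open. The regulator TT8 (AT4G09820, -4.60 ± 0.60, adjusted p = 6.77e-04) fell from 3.07 ± 2.24 to 0.118 ± 0.0478 CPM. The anthocyanin synthesis genes LDOX (AT4G22880, -3.23 ± 0.52), UF3GT (AT5G54060, -3.47 ± 0.52), DFR (AT5G42800, -2.93 ± 0.62) and TT7 (AT5G07990, -2.12 ± 0.37) fell too. Of the list of aliphatic glucosinolate synthesis, which makes the methionine-derived mustard oil precursors, 10 of 20 tested members fell, and 14 fell when adjusted over the list alone. The list was lower (median -1.04, adjusted p = 1.78e-13, and 0.140 with an estimated correlation). The side-chain enzyme gene FMOGS-OX2 (AT1G62540, -1.50 ± 0.24, adjusted p = 0.00263), the core enzyme gene CYP79F1 (AT1G16410, -1.70 ± 0.29, adjusted p = 0.00378) and the regulator MYB76 (AT5G07700, -2.13 ± 0.39) are examples.

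Of the list of the photosynthetic light reactions, 11 of 34 tested members rose, and 20 rose when adjusted over the list alone. The list as a whole was higher (median 0.44, adjusted p = 2.45e-08, and adjusted p = 0.621 with an estimated correlation), with the photosystem genes PSBQ2 (AT4G05180, 0.79 ± 0.12), LHCB1.4 (AT2G34430, 1.18 ± 0.22) and PSAO (AT1G08380, 0.63 ± 0.14) as examples. The Calvin cycle list was lower (median -0.34, adjusted p = 0.0235, call ended in 4 of 8 settings, highest adjusted p = 0.887 with clock covariates, calls among 16 members 0, 0 adjusted over the list alone), with adjusted p = 0.667 with an estimated correlation. The ethylene list was higher (median 0.70, adjusted p = 2.95e-04, calls among 17 members 2 up, 4 up adjusted over the list alone), with adjusted p = 0.0292 with an estimated correlation. The ethylene response factor gene ERF2 (AT5G47220, 1.03 ± 0.26, adjusted p = 0.0307) rose. Of the jasmonate list, 3 of 28 tested members fell, namely VSP2 (AT5G24770, -2.15 ± 0.43, adjusted p = 0.010), VSP1 (AT5G24780, -1.66 ± 0.45) and JMT (AT1G19640, -2.44 ± 0.53), and the list was not called (adjusted p = 0.0896). The defence regulator PAD4 (AT3G52430, 1.23 ± 0.32, adjusted p = 0.0334) and the flowering promoter SOC1 (AT2G45660, 1.02 ± 0.15, adjusted p = 0.00157) rose. The starch phosphorylase gene PHS2 (AT3G46970, 2.42 ± 0.27, adjusted p = 1.71e-04), AT5G62280 (4.49 ± 0.84), AT1G56300 (4.28 ± 0.34), the desaturase gene ADS1 (AT1G06080, 3.63 ± 0.33) and GASA6 (AT1G74670, 3.21 ± 0.71) rose as well, while CSLA01 (AT4G16590, -3.56 ± 0.64) and AT3G22620 (-3.03 ± 0.66) fell.

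Clock genes moved with these gene groups. The evening clock list was higher in TuYV plants (median 1.09, adjusted p = 0.00261, calls among 8 members 2 up, 2 up adjusted over the list alone), with adjusted p = 0.311 with an estimated correlation. The morning list was lower (median -0.84, adjusted p = 0.0161, call ended in 2 of 7 settings, highest adjusted p = 0.0687 without TuYV-0h replicate 3, calls among 6 members 2 down, 2 down adjusted over the list alone), with adjusted p = 0.300 with an estimated correlation. The evening genes GRP7 (AT2G21660, 2.16 ± 0.20, adjusted p = 3.87e-05) and GI (AT1G22770, 2.0 ± 0.39) rose and the morning genes CCA1 (AT2G46830, -0.84 ± 0.19) and LHY (AT1G01060, -1.16 ± 0.29) fell. In all, 697 genes rose and 532 fell of 19515 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A fit to the 6 compared libraries alone called 0 and 0 genes with the same edgeR test, 3011 genes having an unadjusted p below 0.05. With the replicate number as a block as well, chosen after seeing the data, this fit called 737 and 1135, and DESeq2 on all libraries 1170 and 1153. With the clock-list covariates, 288 and 267 genes were called. Leaving out Mock-0h replicate 2, TuYV-0h replicate 1, TuYV-0h replicate 2 or TuYV-0h replicate 3 gave 253 to 488 rising and 149 to 311 falling genes, lowest without Mock-0h replicate 2.

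At 6 h of aphids, the comparison asked how infected and mock plants differed early in infestation. TuYV plants had lower levels of aliphatic glucosinolate genes and of heat shock genes than mock plants. Of the aliphatic glucosinolate list, 11 of 20 tested members fell, and 18 fell when adjusted over the list alone. The list was lower as a whole (median -1.27, adjusted p = 7.03e-32, and adjusted p = 0.0221 with an estimated correlation). The transporter gene BAT5 (AT4G12030, -1.66 ± 0.22, adjusted p = 0.00183) was at 15 ± 2.14 CPM in TuYV and 47.4 ± 7.03 CPM in mock plants, and CYP79F1 (-2.05 ± 0.29, adjusted p = 0.00435) at 45.1 ± 7.03 and 187 ± 46.5 CPM. The pathway regulators MYB29 (AT5G07690, -2.01 ± 0.30, adjusted p = 0.00673) and MYB76 (-2.08 ± 0.37) fell. Of the heat shock list, 8 of 15 tested members fell, and 12 fell when adjusted over the list alone. As a whole the list was lower (median -3.25, adjusted p = 2.14e-19, and adjusted p = 0.0442 with an estimated correlation), including the chaperone genes HSP90.1 (AT5G52640, -3.85 ± 0.72, adjusted p = 0.0206), HSP17.6A (AT5G12030, -3.81 ± 0.81), HSP17.6C (AT1G53540, -3.89 ± 0.85) and HSP23.5 (AT5G51440, -3.30 ± 0.66). The co-chaperone gene Hop3 (AT4G12400, -4.30 ± 0.79, adjusted p = 0.0189) and AT5G48570 (-3.91 ± 0.76), outside the list, fell as well.

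The salicylic acid (median 0.70, adjusted p = 4.33e-05, calls among 21 members 0, 0 adjusted over the list alone) and ethylene lists (median 0.48, adjusted p = 0.0429, call ended in 3 of 8 settings, highest adjusted p = 0.362 without TuYV-6h replicate 1, calls among 17 members 0, 0 adjusted over the list alone) were higher at 6 h. For both lists the test gave adjusted p = 0.319 and 0.237 with an estimated correlation. The abscisic acid list was higher (median 0.57, adjusted p = 0.0431, call ended in 5 of 8 settings, highest adjusted p = 0.373 with clock covariates, which turned the direction, calls among 16 members 0, 0 adjusted over the list alone) and the light-reaction list lower (median -0.23, adjusted p = 1e-04, call ended in 1 of 8 settings, highest adjusted p = 0.264 without TuYV-6h replicate 3, calls among 34 members 0, 4 down adjusted over the list alone). These lists had adjusted p = 0.749 and 0.749 with an estimated correlation. Clock genes moved with these groups. The morning list was lower (median -1.4, adjusted p = 1.15e-06, calls among 6 members 2 down, 3 down adjusted over the list alone) and the evening list higher (median 0.54, adjusted p = 0.00203, calls among 8 members 1 up, 3 up adjusted over the list alone). Tested again, they had adjusted p = 0.0221 and 0.237 with an estimated correlation. CCA1 (-2.23 ± 0.22, adjusted p = 2.63e-04) and RVE8 (AT3G09600, -1.58 ± 0.28) fell and ELF4 (AT2G40080, 1.54 ± 0.28) rose. The starch synthase gene GBSS1 (AT1G32900, -1.28 ± 0.28, adjusted p = 0.0427) and AT1G13650 (-3.82 ± 0.78) fell. FLP1 (AT4G31380, 3.39 ± 0.75, adjusted p = 0.0442), BRU6 (AT4G37390, 2.84 ± 0.62), AT1G21525 (2.63 ± 0.53), RVE2 (AT5G37260, 2.61 ± 0.45) and JMJD5 (AT3G20810, 2.51 ± 0.38) rose. In all, 64 genes rose and 149 fell. The fit to the compared libraries alone called 55 and 225 genes. With the clock-list covariates, 2 and 19 genes were called. Leaving out any 1 of the 6 compared libraries gave 6 to 40 rising and 23 to 86 falling genes, lowest without TuYV-6h replicate 2.

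At 72 h of aphids, the comparison asked how infected and mock plants differed late in infestation. TuYV plants had higher levels of the jasmonate-responsive storage protein genes VSP1 and VSP2 than mock plants. VSP1 (2.98 ± 0.47, adjusted p = 0.00331) was at 323 ± 85.4 CPM in TuYV and 41.0 ± 15 CPM in mock plants, and VSP2 (1.91 ± 0.43, adjusted p = 0.0283) at 649 ± 145 and 173 ± 20.8 CPM, while the jasmonate list was not called (adjusted p = 0.358). The replicate number was used as a block too, since all 3 same-numbered pairs deviated together here. With this block the jasmonate list was lower and the flavonoid list higher (adjusted p = 0.0330 and 0.0177). In the blocked fit these lists had adjusted p = 0.660 and 0.454 with an estimated correlation. Of the starch and sugar list, 2 of 14 tested members rose, and 5 rose and 1 fell when adjusted over the list alone. The list as a whole was higher (median 0.58, adjusted p = 0.0315, call ended in 3 of 8 settings, highest adjusted p = 0.389 without TuYV-72h replicate 3, direction turned with clock covariates at adjusted p = 0.103, and adjusted p = 0.666 with an estimated correlation), with PHS2 (1.66 ± 0.26, adjusted p = 0.00315), and with APL3 (AT4G39210, 0.98 ± 0.23) of starch synthesis. The debranching enzyme gene ISA3 (AT4G09020, 2.65 ± 0.21, adjusted p = 3.86e-05), outside the list, rose too. Of the aliphatic glucosinolate list, 4 of 20 tested members fell, and 10 fell when adjusted over the list alone. The list was lower as a whole (median -0.72, adjusted p = 5.83e-10, call ended in 1 of 8 settings, highest adjusted p = 0.132 with clock covariates, and adjusted p = 0.290 with an estimated correlation), with BAT5 (-1.31 ± 0.22), IPMI1 (AT3G58990, -1.55 ± 0.33), CYP79F2 (AT1G16400, -2.03 ± 0.47) and CYP79F1 (-1.22 ± 0.28). Of the Calvin cycle list, 2 of 16 tested members fell, and 7 fell when adjusted over the list alone. SBPASE (AT3G55800, -0.71 ± 0.14) and GAPB (AT1G42970, -0.65 ± 0.17) fell over all genes tested. This list was lower as a whole (median -0.52, adjusted p = 1.77e-06, call ended in 1 of 8 settings, highest adjusted p = 0.703 with clock covariates, and adjusted p = 0.414 with an estimated correlation).

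The salicylic acid (median 0.43, adjusted p = 0.0432, call ended in 4 of 8 settings, highest adjusted p = 0.298 with clock covariates, calls among 21 members 0, 0 adjusted over the list alone) and senescence lists (median 0.45, adjusted p = 0.0357, call ended in 3 of 8 settings, highest adjusted p = 0.528 with clock covariates, calls among 14 members 0, 0 adjusted over the list alone) were higher at 72 h. They had adjusted p = 0.666 and 0.290 with an estimated correlation. Endoplasmic reticulum stress genes were higher as a list (median 0.38, adjusted p = 9.46e-04, calls among 12 members 0, 5 up adjusted over the list alone), with adjusted p = 0.484 with an estimated correlation. The pathogenesis-related gene PR1 (AT2G14610) was at 323 ± 105 CPM in TuYV and 34.7 ± 13.7 CPM in mock plants, which did not pass the test (3.22 ± 0.95, adjusted p = 0.0879). The defensin gene PDF1.2a (AT5G44420) did not pass either (2.84 ± 0.73, adjusted p = 0.0516), and did with the replicate block (2.86, adjusted p = 0.0290). Clock genes moved with these groups. Evening clock genes were higher as a list (median 1.76, adjusted p = 5.78e-06, calls among 8 members 3 up, 5 up adjusted over the list alone) and morning ones lower (median -0.56, adjusted p = 0.0371, call ended in 3 of 7 settings, highest adjusted p = 0.0989 without TuYV-72h replicate 1, calls among 6 members 2 down, 3 down and 1 up adjusted over the list alone). For both lists the test gave adjusted p = 0.290 and 0.404 with an estimated correlation. PRR5 (AT5G24470, 3.88 ± 0.86, adjusted p = 0.0276), GRP7 (2.0 ± 0.20) and GI (2.11 ± 0.40) rose and LHY (-1.32 ± 0.29) and CCA1 (-0.86 ± 0.19) fell. Rising genes included AT1G56300 (4.15 ± 0.34), AT3G15650 (2.90 ± 0.31) and NATA1 (AT2G39030, 2.62 ± 0.63), and falling ones RL6 (AT1G75250, -2.68 ± 0.40), PAP8 (AT2G01890, -1.93 ± 0.38), PPa2 (AT2G18230, -1.66 ± 0.22) and D27 (AT1G03055, -1.65 ± 0.24).

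In all, 317 genes rose and 207 fell at 72 h in TuYV against mock plants. With the replicate block, 662 and 565 genes were called. Fitted alone, the compared libraries gave 79 and 30 called genes. With the clock-list covariates 688 genes fell. Leaving out any 1 of the 6 compared libraries gave 111 to 215 rising and 46 to 128 falling genes, lowest without Mock-72h replicate 1.

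The virus comparison averaged over the 3 aphid times drew on 9 TuYV and 9 mock libraries. Aliphatic glucosinolate genes were lower and ethylene pathway genes higher in TuYV plants. Of the aliphatic glucosinolate list, 19 of 20 tested members fell, and 19 fell when adjusted over the list alone. As a whole the list was lower (median -1.09, adjusted p = 4.13e-27, and adjusted p = 0.0441 with an estimated correlation), with BAT5 (-1.37 ± 0.12, adjusted p = 9.36e-06), CYP79F1 (-1.66 ± 0.16, adjusted p = 2.27e-05) and MYB29 (-1.30 ± 0.17). Of the ethylene list, 5 of 17 tested members rose, and 7 rose when adjusted over the list alone. The list as a whole was higher (median 0.52, adjusted p = 6.21e-04, and adjusted p = 0.0441 with an estimated correlation), with the receptor genes ERS2 (AT1G04310, 1.18 ± 0.24) and ETR2 (AT3G23150, 1.06 ± 0.27) and the pathogenesis-related genes PR3 (AT3G12500, 0.78 ± 0.19) and PR4 (AT3G04720, 0.86 ± 0.22). The salicylic acid (median 0.50, adjusted p = 6.21e-04, call ended in 1 of 20 settings, highest adjusted p = 0.0583 with clock covariates, calls among 21 members 2 up, 1 up adjusted over the list alone) and senescence lists (median 0.40, adjusted p = 0.0454, call ended in 7 of 20 settings, highest adjusted p = 0.813 with clock covariates, calls among 14 members 3 up, 3 up adjusted over the list alone) were higher, with adjusted p = 0.563 and 0.265 with an estimated correlation. The salicylate-forming enzyme gene ICS1 (AT1G74710, 0.82 ± 0.26, adjusted p = 0.0458), PAD4 (0.74 ± 0.18) and the camalexin enzyme gene PAD3 (AT3G26830, 1.42 ± 0.45, adjusted p = 0.0454) rose. Of the RNA silencing genes, DCL1 (AT1G01040, -0.79 ± 0.15) fell, RDR1 (AT1G14790, 0.37 ± 0.12) and DRB4 (AT3G62800, 0.32 ± 0.10) rose, and AGO2 (AT1G31280) did not pass (0.08 ± 0.15, adjusted p = 0.789).

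The Calvin cycle (median -0.25, adjusted p = 0.00322, call ended in 1 of 20 settings, highest adjusted p = 0.813 with clock covariates, calls among 16 members 5 down, 8 down and 1 up adjusted over the list alone) and heat shock lists (median -0.90, adjusted p = 0.00223, calls among 15 members 2 down, 4 down adjusted over the list alone) were lower on average. Tested again, they had adjusted p = 0.602 and 0.581 with an estimated correlation. At 0, 6 and 72 h, the median was -0.34, 0.04 and -0.52 for the Calvin cycle list (adjusted p = 0.0235, 0.686 and 1.77e-06) and -0.03, -3.25 and 0.58 for the heat shock list (adjusted p = 0.883, 2.14e-19 and 0.358). The flavonoid list was lower (median -0.53, adjusted p = 0.00901, call ended in 1 of 20 settings, highest adjusted p = 0.369 with clock covariates, which turned the direction, calls among 14 members 3 down, 3 down adjusted over the list alone), with adjusted p = 0.572 with an estimated correlation. Its median was -2.43, 0.19 and 0.84 at 0, 6 and 72 h (adjusted p = 6.10e-17, 0.508 and 0.0624). The Rubisco activase gene RCA (AT2G39730, -0.61 ± 0.14), HSP90.1 (-1.35 ± 0.39) and FLS1 (AT5G08640, -1.18 ± 0.22) are examples. The evening clock list was higher (median 0.88, adjusted p = 1.63e-05, calls among 8 members 4 up, 5 up adjusted over the list alone) with GRP7 (1.65 ± 0.11), and had adjusted p = 0.101 with an estimated correlation. The morning list was lower (median -0.86, adjusted p = 6.27e-05, calls among 6 members 3 down, 4 down adjusted over the list alone) with CCA1 (-1.31 ± 0.12), and had adjusted p = 0.0465 with an estimated correlation. FLP1 (2.64 ± 0.41), AT3G15650 (2.37 ± 0.18) and AT4G36430 (2.26 ± 0.27) rose, and NET1B (AT4G14760, -2.20 ± 0.35), CIP1 (AT5G41790, -2.19 ± 0.36) and RL6 (-2.13 ± 0.23) fell. In all, 1581 genes rose and 1374 fell. With the clock-list covariates, 41 and 95 genes were called, and 80 of the 2955 calls remained. The aliphatic glucosinolate (median -0.61, adjusted p = 0.00183), ethylene (adjusted p = 0.0130) and heat shock lists (adjusted p = 8.30e-14) were still called with them at the preset correlation, with adjusted p = 0.793, 0.335 and 0.335 with an estimated correlation. The jasmonate and abscisic acid lists were lower with them (adjusted p = 1.18e-13 and 0.00183), with adjusted p = 0.335 and 0.545 with an estimated correlation. The salicylic acid, senescence, Calvin cycle and flavonoid lists were not called with them (adjusted p = 0.0583, 0.813, 0.813 and 0.369). At 72 h alone, the aliphatic glucosinolate list was not called with them (adjusted p = 0.132).

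The virus comparisons at the 3 times share no library. Between 0 h and 72 h, 168 rising and 71 falling genes were shared, where independent lists would share 11.3 and 5.64. Between 0 h and 6 h, 29 and 46 were shared, against 2.29 and 4.06. Between 6 h and 72 h, 23 and 27 were shared, against 1.04 and 1.58. The virus comparison at 72 h shares no library with 6 h of aphids on mock plants. Of its 317 rising and 207 falling genes, 240 and 155 were shared, against 37.7 and 26.2. Clock lists moved alike in both, and 161 of 524 virus calls remained with clock covariates. The numbers for independent lists may be too low, as estimates of spread are shared.

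**Figure D2:**
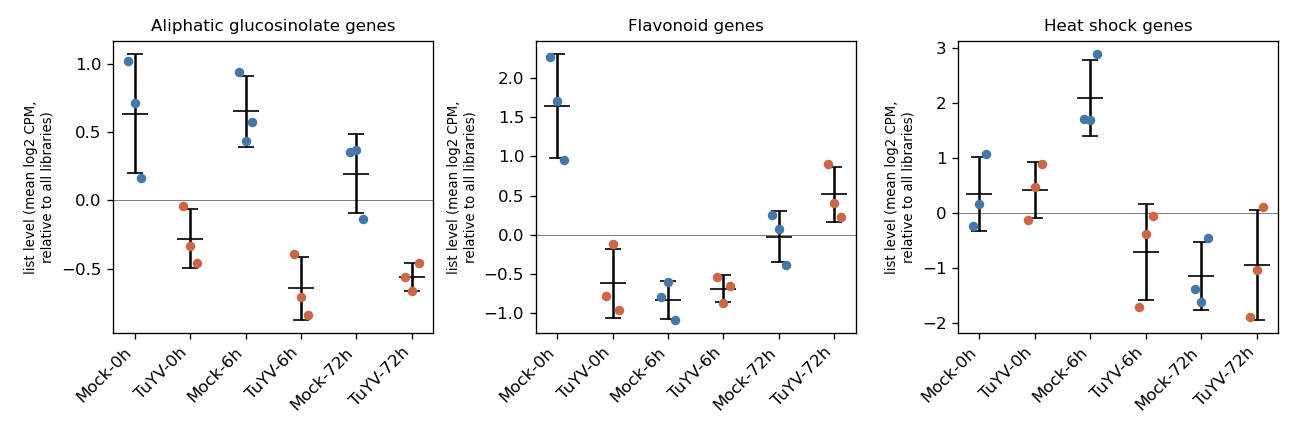
Mean level of 3 gene lists per library, in log2 CPM relative to the mean over all libraries, with 1 point per library, the group mean as a horizontal mark and the SD as error bars (n = 3), mock in blue and TuYV in orange. Aliphatic glucosinolate genes average 0.63 in Mock-0h and -0.28 in TuYV-0h libraries, flavonoid genes 1.64 in Mock-0h and -0.62 in TuYV-0h, and heat shock genes 2.09 in Mock-6h and -0.72 in TuYV-6h.

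What 6 h of aphids changed was asked by comparing infested with uninfested plants of the same inoculum. No uninfested plants of 6 h or 72 h are among the samples, so time and aphids changed together. The share of unaligned reads was higher in the same infested libraries. Clock genes changed strongly in both inocula. All 8 tested evening genes rose and all 6 tested morning genes fell, in mock and in TuYV plants, over all genes tested and adjusted over the list alone. In mock plants the evening list was higher (median 5.05, adjusted p = 2.66e-32) and the morning list lower (median -4.99, adjusted p = 1.11e-24), with adjusted p = 3.85e-04 and 6.89e-05 with an estimated correlation. In TuYV plants the values were the evening list's median 3.87, adjusted p = 2.27e-51 and the morning list's median -5.48, adjusted p = 2.05e-45, with adjusted p = 1.34e-05 and 3.15e-06 with an estimated correlation. FKF1 (AT1G68050, 8.19 ± 0.30, adjusted p = 2.97e-10), a blue-light receptor gene of the flowering pathway, rose from 0.210 ± 0.128 to 62.8 ± 9.26 CPM in mock plants, and by 8.75 ± 0.31 in TuYV plants. CCA1 (-5.52 ± 0.23, adjusted p = 1.10e-09) fell from 295 ± 18.5 to 6.43 ± 1.17 CPM in mock plants, and changed by -6.90 ± 0.25 in TuYV plants. GRP7 (7.71 ± 0.25), ELF4 (7.60 ± 0.45), AT4G33980 (8.83 ± 0.67) and AT1G07050 (8.47 ± 0.65) rose and LHY (-7.57 ± 0.39) and RVE1 (AT5G17300, -5.30 ± 0.43) fell in mock plants.

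**Figure D3:**
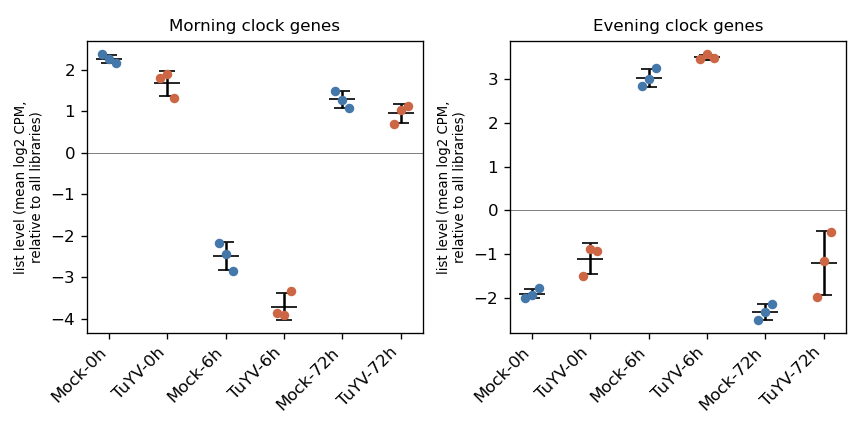
Mean level of the morning and evening clock lists per library, in log2 CPM relative to the mean over all libraries, with 1 point per library, the group mean as a horizontal mark and the SD as error bars (n = 3), mock in blue and TuYV in orange. The morning list averages 2.26 in Mock-0h and -2.48 in Mock-6h libraries, and the evening list -1.90 and 3.03.

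Of the flavonoid list in mock plants at 6 h, 12 of 14 tested members fell, and 12 fell when adjusted over the list alone, including the chalcone synthase gene CHS (AT5G13930, -3.80 ± 0.48, adjusted p = 4.84e-05), CHI (AT3G55120, -2.44 ± 0.28) and TT8 (-3.98 ± 0.55). Of the Calvin cycle list, 10 of 16 tested members fell, and 12 fell when adjusted over the list alone, including FBA1 (AT2G21330, -2.51 ± 0.29, adjusted p = 2.20e-05), SBPASE (-1.44 ± 0.14) and RBCS2B (AT5G38420, -1.74 ± 0.22). Of the light-reaction list, 17 of 34 tested members rose, and 19 rose when adjusted over the list alone, including LHCB1.4 (2.53 ± 0.23) and LHCA2 (AT3G61470, 0.88 ± 0.13). Of the heat shock list, 6 of 15 tested members rose, and 9 rose when adjusted over the list alone, including HSP17.6A (3.35 ± 0.79, adjusted p = 0.00659) and HSP17.8 (AT1G07400, 3.26 ± 0.80). The flavonoid (median -2.53, adjusted p = 3.26e-10) and Calvin cycle lists (median -0.83, adjusted p = 2.21e-07) were lower and the light-reaction (median 0.48, adjusted p = 3.68e-04) and heat shock lists (median 1.90, adjusted p = 0.00312) higher as a whole. These lists had adjusted p = 0.0731, 0.552, 0.868 and 0.868 with an estimated correlation. Starch enzyme genes went both ways: PHS2 (4.30 ± 0.29, adjusted p = 8.26e-08) and SEX1 (AT1G10760, 2.51 ± 0.40) rose and GBSS1 (-4.29 ± 0.31, adjusted p = 1.75e-07) fell.

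Jasmonate genes LOX2 (AT3G45140, -1.85 ± 0.52, adjusted p = 0.0180), VSP2 (-1.58 ± 0.42) and JMT (-2.58 ± 0.53) fell at 6 h in mock plants, as did ALD1 (AT2G13810, -3.39 ± 0.78, adjusted p = 0.00565) and FMO1 (AT1G19250, -2.42 ± 0.74) of the salicylic acid list. Neither list was called (adjusted p = 0.129 and 0.731). RDR1 (1.02 ± 0.20, adjusted p = 0.00183), a polymerase gene of antiviral silencing, and SGS3 (AT5G23570, 1.39 ± 0.28) rose. The RNA silencing list was not called (adjusted p = 0.764). Chaperone genes of the endoplasmic reticulum, BIP2 (AT5G42020, -1.32 ± 0.28) and CNX1 (AT5G61790, -0.75 ± 0.19), fell. In all, 2319 genes rose and 2474 fell. In a fit of only the compared libraries, 1470 and 1654 genes were called. Leaving out Mock-0h replicate 2, Mock-6h replicate 1 or Mock-6h replicate 2 gave 1685 to 2074 rising and 1573 to 1632 falling genes, lowest without Mock-6h replicate 2 and Mock-0h replicate 2.

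Of the Calvin cycle list in TuYV plants at 6 h, 7 of 16 tested members fell, and 8 fell when adjusted over the list alone. The list was lower than at 0 h as a whole (median -0.51, adjusted p = 2.46e-05, and adjusted p = 0.998 with an estimated correlation), with RBCS2B (-1.71 ± 0.22) and RCA (-1.83 ± 0.24). The light-reaction (median -0.17, adjusted p = 0.0303, call ended in 3 of 7 settings, highest adjusted p = 0.9 without TuYV-6h replicate 3, calls among 34 members 5 down and 1 up, 5 down and 1 up adjusted over the list alone) and heat shock lists (median -1.20, adjusted p = 0.0248, call ended in 2 of 7 settings, highest adjusted p = 0.208 without TuYV-6h replicate 1, calls among 15 members 0, 0 adjusted over the list alone) were lower, with adjusted p = 0.998 and 0.998 with an estimated correlation. LHCB2.1 (AT2G05100, -1.99 ± 0.28) and LHCB2.3 (AT3G27690, -1.81 ± 0.26) fell and LHCB1.4 (1.09 ± 0.22) rose. The phloem sucrose exporter gene SWEET12 (AT5G23660, 2.64 ± 0.32, adjusted p = 6.05e-05), the sucrose synthase gene SUS1 (AT5G20830, 1.60 ± 0.35, adjusted p = 0.00867), ABI5 (AT2G36270, 2.15 ± 0.58) and COR27 (AT5G42900, 8.56 ± 0.52) rose, while the phloem and the starch and sugar lists were not called (adjusted p = 0.926 and 0.910). GBSS1 (-5.08 ± 0.32, adjusted p = 7.44e-08), MYB29 (-1.24 ± 0.30), CYP79F2 (-1.90 ± 0.46), AT2G15020 (-6.05 ± 0.65) and BBX31 (AT3G21890, -5.16 ± 0.99) fell. In all, 830 genes rose and 829 fell. The mock and TuYV comparisons share no library, and 724 rising and 625 falling genes were called in both, against 98.6 and 105 for independent lists. These last numbers may be too low, since both comparisons use the same estimate of the spread of each gene. Fitted alone, the compared libraries gave 487 and 465 called genes. Leaving out TuYV-0h replicate 2, TuYV-6h replicate 1 or TuYV-6h replicate 2 gave 525 to 549 rising and 502 to 601 falling genes, lowest without TuYV-6h replicate 1 and TuYV-6h replicate 2.

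What 72 h of aphids changed was asked in the same way, and here too the infested libraries had the higher share of unaligned reads. In mock plants at 72 h, VSP1 (-3.60 ± 0.48, adjusted p = 0.00292) fell from 498 ± 261 to 41.0 ± 15 CPM, VSP2 (-3.03 ± 0.45, adjusted p = 0.00337) from 1413 ± 651 to 173 ± 20.8 CPM, and LOX2 (-2.54 ± 0.54, adjusted p = 0.00906), a lipoxygenase gene of jasmonate synthesis, from 4510 ± 1918 to 776 ± 287 CPM. Of the jasmonate list, 4 of 28 tested members fell and 2 rose, and 4 fell and 2 rose when adjusted over the list alone, and it was not called (adjusted p = 0.0588). Of the abscisic acid list, 8 of 16 tested members fell, and 8 fell when adjusted over the list alone. As a whole the list was lower (median -2.20, adjusted p = 7.35e-04, and adjusted p = 0.416 with an estimated correlation), including the phosphatase genes ABI1 (AT4G26080, -2.87 ± 0.73, adjusted p = 0.0172), ABI2 (AT5G57050, -2.87 ± 0.67) and HAB1 (AT1G72770, -2.40 ± 0.55), which curb abscisic acid signalling. HAI1 (AT5G59220, -4.17 ± 1.27), another phosphatase gene, and BSMT1 (AT3G11480, -4.22 ± 1.0, adjusted p = 0.0133), which makes methyl salicylate, fell. The abscisic acid receptor gene PYL5 (AT5G05440, 2.54 ± 0.53, adjusted p = 0.00876) rose.

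Of the light-reaction list, 26 of 34 tested members rose, and 29 rose when adjusted over the list alone, including PSAL (AT4G12800, 0.70 ± 0.14) and PSAO (0.73 ± 0.14). Of the early defence list, 5 of 26 tested members rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone, including WRKY22 (AT4G01250, 1.41 ± 0.31, adjusted p = 0.0106), MPK11 (AT1G01560, 2.25 ± 0.52) and CML38 (AT1G76650, 2.05 ± 0.46), while CML39 (AT1G76640, -2.63 ± 0.68) fell. Both were higher as a whole (light reactions median 0.62, adjusted p = 3.93e-12, early defence median 0.96, adjusted p = 2.12e-04), with adjusted p = 0.416 and 0.257 with an estimated correlation. The Calvin cycle (median 0.25, adjusted p = 0.0372, call ended in 3 of 7 settings, highest adjusted p = 0.158 without Mock-0h replicate 3, calls among 16 members 0, 0 adjusted over the list alone) and ethylene lists (median 0.84, adjusted p = 0.00357, calls among 17 members 4 up, 4 up adjusted over the list alone) were higher as well. They had adjusted p = 0.687 and 0.209 with an estimated correlation. The salicylic acid list was higher (median 0.56, adjusted p = 0.0177, call ended in 3 of 7 settings, highest adjusted p = 0.197 without Mock-0h replicate 1, calls among 21 members 2 up, 0 adjusted over the list alone), with adjusted p = 0.586 with an estimated correlation. The ethylene pathway genes ORA59 (AT1G06160, 3.69 ± 0.87, adjusted p = 0.0130) and ACS7 (AT4G26200, 3.07 ± 0.96) and the salicylic acid genes PAD4 (1.06 ± 0.32) and NPR1 (AT1G64280, 0.56 ± 0.17) rose.

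Lower as a whole in mock plants at 72 h were the flavonoid (median -1.58, adjusted p = 4.02e-07, calls among 14 members 8 down, 13 down adjusted over the list alone) and heat shock lists (median -1.82, adjusted p = 0.00217, calls among 15 members 4 down, 6 down adjusted over the list alone). For both lists the test gave adjusted p = 0.257 and 0.586 with an estimated correlation. Also lower were the aliphatic glucosinolate (median -0.40, adjusted p = 0.00543, call ended in 2 of 7 settings, highest adjusted p = 0.197 without Mock-0h replicate 1, calls among 20 members 3 down, 3 down adjusted over the list alone) and phloem lists (median -0.56, adjusted p = 0.00543, calls among 13 members 4 down, 6 down adjusted over the list alone). Tested again, they had adjusted p = 0.586 and 0.416 with an estimated correlation. The RNA silencing (median -0.34, adjusted p = 0.0175, call ended in 2 of 7 settings, highest adjusted p = 0.197 without Mock-0h replicate 1, calls among 17 members 3 down, 3 down adjusted over the list alone) and starch and sugar lists (median -0.61, adjusted p = 0.0239, call ended in 2 of 7 settings, highest adjusted p = 0.158 without Mock-0h replicate 3, calls among 14 members 4 down, 4 down adjusted over the list alone) were lower too. These lists had adjusted p = 0.586 and 0.586 with an estimated correlation. The morning clock list was lower (median -0.85, adjusted p = 0.0103, call ended in 1 of 7 settings, highest adjusted p = 0.0610 without Mock-0h replicate 1, calls among 6 members 3 down, 3 down adjusted over the list alone), with adjusted p = 0.291 with an estimated correlation. Examples are TT8 (-3.02 ± 0.52), HSP101 (AT1G74310, -2.63 ± 0.80), MYB76 (-2.18 ± 0.39), SWEET12 (-1.77 ± 0.32), DCL1 (-1.37 ± 0.27), SEX1 (-1.92 ± 0.39) and PRR9 (AT2G46790, -2.40 ± 0.68). CSLA01 (-5.38 ± 0.72) fell and AT5G38700 (3.31 ± 0.73) and ZAT7 (AT3G46090, 2.79 ± 0.83) rose. In all, 1661 genes rose and 2094 fell. The fit to the compared libraries alone called 381 and 1205 genes. Leaving out Mock-0h replicate 2, Mock-72h replicate 1, Mock-72h replicate 2 or Mock-72h replicate 3 gave 321 to 1078 rising and 639 to 1022 falling genes, lowest without Mock-0h replicate 2.

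In TuYV plants, few genes were called at 72 h of aphids against 0 h, while the share of unaligned reads was higher. AT2G42310 (0.72 ± 0.10, adjusted p = 0.0279) rose. FAR1 (AT5G22500, -2.29 ± 0.29, adjusted p = 0.0239), a fatty acyl reductase gene, SQP1 (AT5G24150, -1.50 ± 0.21, adjusted p = 0.0279), SPS2 (AT1G17050, -1.04 ± 0.15, adjusted p = 0.0292) and AT5G61350 (-2.01 ± 0.31, adjusted p = 0.0375) fell, the last being named after its values were seen. PR1 was at 36.5 ± 7.72 CPM at 0 h and 323 ± 105 CPM at 72 h and did not pass the test (3.14 ± 0.95, adjusted p = 0.197), and neither did PDF1.2a (4.13 ± 0.82, adjusted p = 0.0860). All 3 same-numbered pairs deviated together in this comparison too. With the replicate number as a block, PDF1.2a (4.15, adjusted p = 0.0334) rose and CCA1 (-1.05, adjusted p = 0.0228) fell. As lists, flavonoid (median 1.45, adjusted p = 5.16e-07, calls among 14 members 0, 7 up adjusted over the list alone) and light-reaction genes (median 0.26, adjusted p = 5.42e-06, calls among 34 members 0, 0 adjusted over the list alone) were higher, with adjusted p = 0.268 and 0.558 with an estimated correlation. So were salicylic acid (median 0.52, adjusted p = 9.39e-04, calls among 21 members 0, 0 adjusted over the list alone) and ethylene genes (median 0.11, adjusted p = 0.0390, calls among 17 members 0, 4 up and 1 down adjusted over the list alone). They had adjusted p = 0.508 and 0.305 with an estimated correlation. Senescence (median 0.50, adjusted p = 0.0354, call ended in 2 of 7 settings, highest adjusted p = 0.272 without TuYV-0h replicate 1, calls among 14 members 0, 1 up adjusted over the list alone) and endoplasmic reticulum stress genes (median 0.30, adjusted p = 0.0334, call ended in 1 of 7 settings, highest adjusted p = 0.283 without TuYV-0h replicate 3, calls among 12 members 0, 0 adjusted over the list alone) were higher too. For both lists the test gave adjusted p = 0.305 and 0.558 with an estimated correlation. Heat shock (median -1.35, adjusted p = 3.79e-05, calls among 15 members 0, 0 adjusted over the list alone) and abscisic acid lists (median -1.04, adjusted p = 0.00186, call ended in 1 of 7 settings, highest adjusted p = 0.135 without TuYV-0h replicate 3, calls among 16 members 0, 0 adjusted over the list alone) were lower, with adjusted p = 0.508 and 0.508 with an estimated correlation. So were the phloem (median -0.27, adjusted p = 0.0218, call ended in 3 of 7 settings, highest adjusted p = 0.272 without TuYV-0h replicate 1, calls among 13 members 0, 0 adjusted over the list alone) and starch and sugar lists (median -0.37, adjusted p = 0.0334, call ended in 3 of 7 settings, highest adjusted p = 0.487 without TuYV-0h replicate 3, calls among 14 members 0, 1 down adjusted over the list alone). These had adjusted p = 0.508 and 0.558 with an estimated correlation. Aliphatic glucosinolate (median -0.26, adjusted p = 0.0459, call ended in 3 of 7 settings, highest adjusted p = 0.398 without TuYV-0h replicate 1, calls among 20 members 0, 1 down adjusted over the list alone) and morning clock lists (median -0.60, adjusted p = 0.00186, calls among 6 members 0, 1 down adjusted over the list alone) were also lower. These had adjusted p = 0.629 and 0.268 with an estimated correlation. With the replicate block the jasmonate list was lower and the early defence list higher (adjusted p = 4.92e-04 and 0.0280, and adjusted p = 0.450 and 0.527 with an estimated correlation in this fit), and the call of the aliphatic glucosinolate list ended (adjusted p = 0.0605).

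In all, 1 gene rose and 4 fell in TuYV plants at 72 h, with 2721 genes at an unadjusted p below 0.05. Of the genes called in mock plants at 72 h, 85.3% of the rising and 91.6% of the falling ones had the same sign in TuYV plants, which share no library with them. With the replicate block, 84 and 92 genes were called. The fit to the compared libraries alone called 0 and 0 genes with the edgeR test, 1463 having an unadjusted p below 0.05, and DESeq2 on all libraries 192 and 184. Leaving out TuYV-0h replicate 1, TuYV-0h replicate 3, TuYV-72h replicate 1, TuYV-72h replicate 2 or TuYV-72h replicate 3 gave 0 to 4 rising and 0 to 7 falling genes, lowest without TuYV-0h replicate 1 and TuYV-72h replicate 1. Where 0 genes rose, between 1279 and 2853 genes had an unadjusted p below 0.05 in the edgeR test.

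Whether aphids changed expression differently in TuYV and mock plants was tested by the interaction, the change in TuYV plants minus that in mock plants. Flavonoid genes had a higher value in TuYV plants at both times. At 6 h, 4 of 14 tested flavonoid genes passed and 11 when adjusted over the list alone, with TT8 (4.79 ± 0.93, adjusted p = 0.0395) and UF3GT (4.22 ± 0.73) among them. At 72 h, 2 of 14 tested flavonoid genes passed and 11 when adjusted over the list alone. Those that passed over all genes tested were UF3GT (4.67 ± 0.71, adjusted p = 0.0160) and LDOX (4.05 ± 0.70). The list median was 2.49 at 6 h (adjusted p = 4.65e-19) and 3.41 at 72 h (adjusted p = 1.44e-27). With an estimated correlation, adjusted p was 0.0235 and 0.00524. The heat shock list had a lower value at 6 h (median -3.15, adjusted p = 3.58e-16, calls among 15 members 0, 12 down adjusted over the list alone), with adjusted p = 0.116 with an estimated correlation. Its mean level was 2.09 ± 0.69 in Mock-6h and -0.72 ± 0.88 in TuYV-6h libraries (log2 scale, SD, n = 3). The light-reaction list was lower (median -0.71, adjusted p = 4.65e-19, calls among 34 members 0, 22 down adjusted over the list alone), and the abscisic acid (median 0.65, adjusted p = 0.0260, call ended in 4 of 13 settings, highest adjusted p = 0.189 without Mock-0h replicate 3, calls among 16 members 0, 0 adjusted over the list alone) and Calvin cycle lists (median 0.26, adjusted p = 0.0116, call ended in 3 of 13 settings, highest adjusted p = 0.124 without Mock-0h replicate 1, calls among 16 members 0, 0 adjusted over the list alone) higher at 6 h. These lists had adjusted p = 0.413, 0.607 and 0.638 with an estimated correlation. At 72 h the light-reaction (median -0.35, adjusted p = 1.10e-05, calls among 34 members 0, 0 adjusted over the list alone) and early defence lists (median -0.87, adjusted p = 0.00116, calls among 26 members 0, 0 adjusted over the list alone) were lower and the endoplasmic reticulum stress list higher (median 0.64, adjusted p = 4.98e-04, calls among 12 members 0, 0 adjusted over the list alone). Tested again, they had adjusted p = 0.780, 0.468 and 0.746 with an estimated correlation.

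The storage protein genes VSP1 (4.63 ± 0.65, adjusted p = 0.0111) and VSP2 (4.06 ± 0.61, adjusted p = 0.0147) had an interaction at 72 h. VSP2 was at 319 ± 194 CPM at 0 h and 649 ± 145 CPM at 72 h in TuYV plants, where it did not pass the test (1.03 ± 0.42, adjusted p = 0.303), and fell in mock plants. CSLA01 (7.12 ± 0.95, adjusted p = 0.00897) had a higher value and ADS1 (-3.57 ± 0.44, adjusted p = 0.00521), FAR1 (-2.33 ± 0.40), AT1G12080 (-1.77 ± 0.25), AT5G22580 (-1.71 ± 0.30) and AT1G18360 (-0.85 ± 0.14) a lower one. At 6 h ABCC4 (AT2G47800, 3.08 ± 0.37, adjusted p = 0.00349), BHLH100 (AT2G41240, 3.48 ± 0.56) and RVE2 (3.16 ± 0.61) had a higher value. AT1G56300 (-4.32 ± 0.43, adjusted p = 8.78e-04), HSP70T-2 (AT2G32120, -3.27 ± 0.57), PHS2 (-2.62 ± 0.36), CCA1 (-1.38 ± 0.29) and GRP7 (-1.39 ± 0.27) had a lower one. In all, 33 genes were higher and 61 lower at 6 h, and 13 and 6 at 72 h. The fit to the compared libraries alone called 7 and 20 genes at 6 h and 2 and 1 at 72 h. Leaving out Mock-0h replicate 2, Mock-6h replicate 1, Mock-6h replicate 2, Mock-6h replicate 3, TuYV-0h replicate 1, TuYV-0h replicate 2, TuYV-6h replicate 2 or TuYV-6h replicate 3 gave 7 to 15 higher and 25 to 43 lower genes at 6 h, lowest without Mock-0h replicate 2 and TuYV-6h replicate 2. Leaving out Mock-0h replicate 1, Mock-0h replicate 2, Mock-72h replicate 1, Mock-72h replicate 2, Mock-72h replicate 3, TuYV-0h replicate 1, TuYV-72h replicate 1, TuYV-72h replicate 2 or TuYV-72h replicate 3 gave 5 to 13 higher and 2 to 11 lower genes at 72 h, lowest without Mock-72h replicate 1 and Mock-0h replicate 2.

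The jasmonate, camalexin, indole glucosinolate, guard cell and epidermis lists were not called in any of the 10 comparisons in the fit to all libraries without a block. Their lowest adjusted p over the comparisons were 0.0588, 0.0954, 0.358, 0.107 and 0.0730. Each was called in at least 1 comparison in other settings, with lowest adjusted p of 1.18e-13, 0.0170, 0.0364, 0.0317 and 0.00740. The flowering list had 3 tested members and was not tested as a list. The p-values measure only the spread between these samples, since the labels do not say that the libraries come from separate plants.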

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

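The tests of virus reads, of aphid RNA and of growth or harvest conditions were chosen after the results they concern were seen. The interaction, a test of whether aphids changed expression differently in TuYV and mock plants, called 94 genes at 6 h and 19 genes at 72 h. Chance is not excluded for these counts, since 5 and 6 of 100 splits of the samples, the real one included, called as many or more, and the highest others called 930 and 1626. With each compared library left out in turn, 7 to 38 genes were higher and 25 to 89 lower at 6 h, and 5 to 15 and 2 to 11 at 72 h. Values are log2 differences, the change in TuYV minus the change in mock plants. At 6 h the list medians were 0.65 for abscisic acid, -0.71 for light reactions, 0.26 for the Calvin cycle, -3.15 for heat shock and 2.49 for flavonoid genes. At 72 h they were -0.35 for light reactions, -0.87 for early defence, 0.64 for endoplasmic reticulum stress and 3.41 for flavonoid genes.

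Named genes with a positive log2 difference at 6 h were CSLA01 (5.79), TT8 (4.79), UF3GT (4.22), BHLH100 (3.48), LDOX (3.42), RVE2 (3.16), ABCC4 (3.08) and CHI (1.89). Negative ones were found for AT1G56300 (-4.32), AT5G49015 (-3.28), HSP70T-2 (-3.27), AT4G16880 (-3.20), ADS1 (-2.92), PHS2 (-2.62), GRP7 (-1.39) and CCA1 (-1.38). At 72 h CSLA01 (7.12), UF3GT (4.67), VSP1 (4.63), VSP2 (4.06) and LDOX (4.05) had a higher value. ADS1 (-3.57), FAR1 (-2.33), AT1G12080 (-1.77), AT5G22580 (-1.71) and AT1G18360 (-0.85) had a lower one.

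Flavonoid genes changed differently with aphids in the 2 inocula, and their level was 1.64 ± 0.66 in Mock-0h, -0.83 ± 0.24 in Mock-6h, -0.02 ± 0.33 in Mock-72h, -0.62 ± 0.44 in TuYV-0h, -0.69 ± 0.17 in TuYV-6h and 0.52 ± 0.35 in TuYV-72h libraries (log2 scale, SD, n = 3). A single Mock-0h library does not account for it, since the list kept its call at 72 h without each Mock-0h library in turn, with an adjusted p of 7.47e-16 at most. In every comparison with Mock-0h, its growth or harvest conditions and the group are the same samples and cannot be told apart. Its lowest library lay 0.0431 above the highest of the other 5 groups on the log2 scale. An effect of virus and aphids together stays open and untested beside it.

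Reads that did not align were found above the level of libraries without aphids, at 3.47% in Mock-6h, 2.94% in Mock-72h, 3.90% in TuYV-6h and 4.85% in TuYV-72h libraries. Reads of the virus do not account for this, since Mock-6h exceeded Mock-0h by 2.59 percentage points with every Mock-6h library above every Mock-0h library, and mock libraries held no viral count. RNA of aphids left on the leaves is a candidate source for the 2.86 percentage points between libraries with and without aphids. It stays open because the files hold no read sequences. A change in the plants' own transcripts with aphids was not tested. Viral counts, which the comparisons do not use, were 4.75, 4.34 and 4.59 CPM of the plant counts in TuYV libraries at 0, 6 and 72 h and 0 in mock libraries.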

How the results depend on the processing

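The fits with clock-list covariates, the fit with the replicate block on only the compared groups and both the block and the covariates with an estimated correlation were chosen after seeing the data. Named-gene values kept their side of the threshold, and their direction where called, in 409 of 413 cases with RLE scaling and 381 of 413 with no filter on low counts. These values did so in 352 of 358 cases with the stricter filter, 402 of 413 with the replicate block and 413 of 413 without organelle genes. They did so in 222 of 341 cases in fits to only the compared groups, 42 of 44 with the block as well, 53 of 169 with the clock-list covariates, 400 of 413 with DESeq2 and 2774 of 3498 with libraries left out 1 at a time. With the clock-list covariates the averaged virus values turned to 0.0985 for LHY, -0.0173 for PP2-A1 and -0.620 for PRR5, the only named-gene values to turn in the settings run. RLE scaling moved the median of all genes by -0.0216 at most on the log2 scale. Counts of genes called up and down with RLE scaling and without organelle genes lay within 1.5 times the reported ones in all 10 comparisons. With RLE scaling between 78.9% (interaction at 72 h, 15 of 19) and 100% of the calls were kept. Of the 37336 plant genes, 19515 had counts enough to be tested, and nothing can be said of the others at this depth.

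With the replicate block, genes called up and down numbered 1306 and 1174 for the virus without aphids, 191 and 394 for the virus at 6 h, 662 and 565 for the virus at 72 h, 3062 and 3202 for aphids 72 h on mock plants and 1358 and 1394 for aphids 6 h on TuYV plants. They further numbered 84 and 92 for aphids 72 h on TuYV plants, 102 and 240 for the interaction at 6 h, 51 and 46 for the interaction at 72 h and 2325 and 2298 for the averaged virus comparison. In fits to only the compared groups they numbered 0 and 0 for the virus without aphids, 55 and 225 for the virus at 6 h, 79 and 30 for the virus at 72 h, 1470 and 1654 for aphids 6 h on mock plants and 381 and 1205 for aphids 72 h on mock plants. Other counts were 487 and 465 for aphids 6 h on TuYV plants, 0 and 0 for aphids 72 h on TuYV plants, 7 and 20 for the interaction at 6 h and 2 and 1 for the interaction at 72 h. At the counts of 0, this edgeR test had 3011 genes (virus without aphids) and 1463 genes (aphids 72 h on TuYV plants) at an unadjusted p below 0.05. The block and only the compared groups together gave 737 and 1135 for the virus without aphids. DESeq2 called 1170 and 1153 for the virus without aphids, 292 and 446 for the virus at 6 h, 663 and 644 for the virus at 72 h, 192 and 184 for aphids 72 h on TuYV plants and 178 and 273 for the interaction at 6 h. Further counts were 88 and 105 for the interaction at 72 h. The clock-list covariates gave 288 and 267 for the virus without aphids, 2 and 19 for the virus at 6 h, 342 and 688 for the virus at 72 h and 41 and 95 for the averaged virus comparison. No filter gave 0 and 2 for aphids 72 h on TuYV plants and 19 and 41 for the interaction at 6 h, with 2856 genes of the former at an unadjusted p below 0.05. The stricter filter gave 41 and 136 for the virus at 6 h, 2 and 3 for aphids 72 h on TuYV plants and 40 and 93 for the interaction at 6 h.

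With each library of the compared groups left out in turn, genes called up and down ranged over 253 to 857 and 149 to 673 for the virus without aphids, 6 to 40 and 23 to 86 for the virus at 6 h, 111 to 215 and 46 to 128 for the virus at 72 h, 1685 to 2435 and 1573 to 2511 for aphids 6 h on mock plants and 321 to 2431 and 639 to 2578 for aphids 72 h on mock plants. The setting also gave 525 to 791 and 502 to 715 for aphids 6 h on TuYV plants, 0 to 4 and 0 to 7 for aphids 72 h on TuYV plants, 7 to 38 and 25 to 89 for the interaction at 6 h and 5 to 15 and 2 to 11 for the interaction at 72 h. Where such a count was 0, between 1279 and 2853 genes had an unadjusted p below 0.05 in the edgeR test. Lists called up and down ranged over 3 to 5 and 3 to 6 for the virus without aphids, 4 to 9 and 2 to 4 for the virus at 72 h, 3 to 4 and 3 to 5 for aphids 6 h on mock plants, 3 to 5 and 6 to 9 for aphids 72 h on mock plants and 1 and 2 to 4 for aphids 6 h on TuYV plants. Also counted were 1 to 4 and 2 to 5 for the interaction at 6 h and 2 to 6 and 2 to 4 for the interaction at 72 h. With a correlation estimated for each list, camera called 1 and 1 for the virus without aphids, 0 and 3 for the virus at 6 h, 0 and 0 for the virus at 72 h, 1 and 1 for aphids 6 h on mock plants and 0 and 0 for aphids 72 h on mock plants. Further values were 1 and 1 for aphids 6 h on TuYV plants, 0 and 0 for aphids 72 h on TuYV plants, 1 and 0 for the interaction at 6 h, 1 and 0 for the interaction at 72 h and 1 and 2 for the averaged virus comparison. In the 6 comparisons with a count of 0 there, 4, 3, 3, 2, 2 and 1 lists had an unadjusted p below 0.05, in the order just given. The clock-list covariates gave 1 list up and 4 down in the averaged virus comparison. In the virus comparisons they added the calls, with adjusted p in brackets, of lower lists for jasmonate on average, at 0 h, at 6 h and at 72 h (1.18e-13, 1.16e-09, 9.51e-08 and 7.42e-12), abscisic acid on average, at 0 h and at 72 h (0.00183, 3.58e-04 and 0.00356), heat shock at 0 h and at 72 h (4.35e-04 and 4.10e-04) and starch and sugar at 6 h (0.0132). Higher lists they added were RNA silencing at 6 h (0.0336), flavonoid at 6 h and at 72 h (0.00124 and 0.00102), light reactions at 72 h (0.0162) and epidermis at 72 h (0.0344). These added lists had adjusted p of 0.335 to 0.826 with an estimated correlation. With it and the covariates camera called 0 and 0 for the virus without aphids, 0 and 1 for the virus at 6 h, 0 and 0 for the virus at 72 h and 0 and 0 for the averaged virus comparison. In these 4 comparisons 1, 1, 0 and 3 lists had an unadjusted p below 0.05. The replicate block called the jasmonate list down in 8 comparisons, against 0 without it, with adjusted p = 0.450 to 0.964 with an estimated correlation in the blocked fit. It also called the early defence list (virus without aphids, aphids 72 h on TuYV plants), the flavonoid list (virus at 72 h), the aliphatic glucosinolate list (interaction at 6 h) and the ethylene and abscisic acid lists (interaction at 72 h). It ended the calls of the ethylene list (virus at 6 h), the aliphatic glucosinolate list (aphids 72 h on TuYV plants) and the senescence list (averaged virus), and no other list call changed. With the block and an estimated correlation, camera called 0 and 1 for the virus without aphids, 0 and 3 for the virus at 6 h, 0 and 0 for the virus at 72 h, 1 and 1 for aphids 6 h on mock plants and 0 and 0 for aphids 72 h on mock plants. The remaining counts were 1 and 1 for aphids 6 h on TuYV plants, 0 and 0 for aphids 72 h on TuYV plants, 1 and 1 for the interaction at 6 h, 1 and 0 for the interaction at 72 h and 0 and 1 for the averaged virus comparison. In the 7 of these with a count of 0, 3, 4, 2, 4, 4, 1 and 5 lists had an unadjusted p below 0.05. The cause was not tested, except that the fits to only the compared groups and those without a library used fewer samples.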

Other observations

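The test of scaling was chosen after the result it concerns was seen. Markers of other cell types moved singly while their lists were not called, except for phloem at 72 h of aphids, in the fit to all libraries without a block. In TuYV plants without aphids, the wax synthesis gene CER3 (AT5G57800, -1.08 ± 0.25) of the epidermis, the myrosinase gene TGG1 (AT5G26000, -0.64 ± 0.14) of guard and myrosin cells, and SWEET12 (-1.36 ± 0.31) of the phloem fell. The epidermal wax genes CER3 (-1.41 ± 0.25), FDH (AT2G26250, -0.98 ± 0.18) and CER6 (AT1G68530, -1.27 ± 0.32) fell at 6 h of aphids on mock plants. At 72 h of aphids on mock plants, the phloem genes SUS6 (AT1G73370, -2.0 ± 0.49), AHA3 (AT5G57350, -0.83 ± 0.19) and CALS7 (AT1G06490, -1.19 ± 0.38) fell, and the guard cell markers TGG1 (-0.44 ± 0.14) and GC1 (AT1G22690, 0.65 ± 0.22) went opposite ways. The flowering repressor FLC (AT5G10140, -1.61 ± 0.34) fell and SOC1 (0.46 ± 0.15) rose.

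Senescence genes went both ways with aphids. At 6 h on mock plants, the chlorophyll breakdown gene NYC1 (AT4G13250, 1.39 ± 0.17) and SEN1 (2.44 ± 0.38) rose while SAG13 (AT2G29350, -2.32 ± 0.38) and the regulator NAP (AT1G69490, -3.0 ± 0.53) fell. On TuYV plants at 6 h, NYC1 (1.52 ± 0.18) and SEN1 (1.41 ± 0.36) rose and NAP (-2.36 ± 0.51) fell as well. In TuYV plants without aphids, SAG21 (1.36 ± 0.30) and SEN1 (1.39 ± 0.37) rose.

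Aliphatic glucosinolate genes were lower in TuYV than in mock plants (averaged median -1.09). Unequal scaling of the libraries moves every gene alike and drops out of the difference between this list and all tested genes. The list median lay -1.09 from that of all tested genes, the value nearer 0 of TMM and RLE scaling. With both, the upper quartile of the list (-0.73 and -0.73) lay below the lower quartile of all tested genes (-0.22 and -0.22), so unequal scaling does not account for the difference. A difference in clock phase at harvest stays open. With the clock-list levels as covariates the list median was -0.61 (adjusted p = 0.00183, and adjusted p = 0.793 with an estimated correlation), which met the bound set beforehand against this explanation, but by less than the spread of the members (quartiles -0.95 and -0.24), a condition added after the value was seen. At 72 h alone the call ended with them, the median going from -0.72 (quartiles -1.04 and -0.35) to -0.31 (quartiles -0.86 and -0.01, adjusted p = 0.132). An effect of the virus stays open beside it.

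The comparisons of 3 against 3 libraries allow 10 splits each, too few for a share under 0.05. For the virus without aphids, 2 splits called as many genes as the real one or more, which called 1229, and the highest other called 1302. That split set Mock-0h replicate 1 and TuYV-0h replicates 1 and 2 against the rest. For the virus and for aphids on mock and on TuYV plants, each at 6 h and 72 h, only the real split did so. The real ones called 213, 524, 4793, 3755, 1659 and 5 genes, and the highest others 0 in the edgeR test. Of 100 splits, 5 (interaction at 6 h) and 6 (at 72 h) called at least the real 94 and 19 genes. The highest others called 930 and 1626. Chance is therefore not excluded for either number of genes. Both highest splits grouped the 0 h libraries as the split with 1302 genes did, while some others that did so called 0. The cause was not tested. For the averaged virus comparison only the real split of 100 called 2955 genes, and the highest other called 592. Chance is unlikely, though the splits ignore replicate numbers.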
